A study of Homo sapiens with 6 samples.

How the data were processed

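The data are one table of values for 6 Affymetrix arrays of A375 cells, each hybridised with labelled cRNA made from total RNA, per the labels' protocols. The deposited values are probe set intensity values on a linear scale, and RMA is the only tool that the submitters' processing notes name. Its version, whether all arrays were normalized together, and any step after it are not given in the sources used here. RMA gives log2 values, so the intensities had been taken back to the linear scale before they were deposited. Each array was assigned to its condition from its label, and each condition had 1 array, so no replicate number pairs arrays.

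The table held 54675 probe sets. Gene names came from the platform annotation, in which 41097 probe sets had 1 gene symbol, 1801 had several and 11777 were not listed. Probe sets with several symbols or none were not named here. All 19734 symbols that could be checked through gene identifiers equalled the current RefSeq symbols.

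The values of the 6 h arrays did not sit on the same rows as those of the 16 h arrays throughout. In 6 blocks of the table, 1118 probe sets (2.05%) carried 6 h values that belonged to another row of the block. It was as if the 6 h values had been sorted with punctuation before the digits and the identifiers the other way. Over these probe sets the DMSO arrays at 6 h and 16 h had an r of 0.455 as deposited and 0.984 once the 6 h values were placed in the other order, against 0.992 for the other 53495 probe sets. The 1118 probe sets and 62 control probe sets were therefore left out of every comparison, a choice made after seeing the data, and keeping them as deposited or with the order restored were added as alternatives. Leaving them out removed 99 genes, DDIT4 among them, and moved 192 genes to another probe set or out of the analysis.

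Values were converted to log2. For a gene with several probe sets, the probe set with the highest mean over the 6 arrays was used, which gave 19676 genes. There were 7 differences, each as treated minus control: vemurafenib minus DMSO at 6 h and at 16 h, AT9283 minus DMSO, the combination minus DMSO, minus vemurafenib and minus AT9283 at 6 h, and DMSO at 16 h minus DMSO at 6 h. The interaction was the combination minus AT9283 less vemurafenib minus DMSO. A gene passed the size rule with a difference of at least 1 on the log2 scale, which is 2-fold, and a log2 value of at least 6 on the higher array. This is a rule of size and not a test, and no p-value was computed across genes from single arrays. Array quality was checked through the 3' and 5' probe sets of ACTB and GAPDH, whose log2 differences lay between -0.28 and 0.16.

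Before the data were examined, 22 gene lists were fixed: 4 of the ATF4 program (stress regulators, amino acid synthesis, amino acid transport, tRNA charging), eIF2α kinases and phosphatase, ER chaperones, ERK pathway output, mitosis, DNA replication, JAK-STAT feedback targets, interferon-stimulated genes, pigment cell differentiation, undifferentiated melanoma state, p53 targets, glycolysis and hypoxia, cholesterol synthesis, NRF2 targets, ribosome biogenesis, lysosome and autophagy, BCL2 family, markers of other lineages, and housekeeping genes. Of 396 list entries 361 were measured. A list's median was given as its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins, as a description of these arrays. It was said to stand apart when it lay among the lowest or highest 0.5% of them. Named genes followed a rule fixed at the same time. This rule covers the 8 highest and 8 lowest genes over the size rule per comparison, leaving out uncharacterised and non-coding symbols, and up to 4 members of each list over the size rule. It also covers 20 genes chosen for the question, ATF4, DDIT3, ASNS and DUSP6 among them. The text does not print every gene that the rule covers. Genes outside it are marked as chosen after their values were seen.

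Correlations between comparisons were computed across 8885 genes with a mean log2 of at least 6. For comparisons that share an array, 20 simulated sets of unchanged arrays, with an array SD of 0.16 taken from the DMSO pair, gave the value without effect, and since that pair also holds time, the simulated values are upper estimates. Limma with a trended prior was fitted to the 4 DMSO and vemurafenib arrays with time as a block, and to all 6 arrays with main effects of vemurafenib, AT9283 and time, the latter also with the interaction of the drugs (added after seeing the data, 1 residual degree of freedom that also holds the change of the vemurafenib effect with time), on genes with at least 1 array at the floor, with Benjamini-Hochberg adjustment.

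The steps were tested on simulated data. For vemurafenib at 6 h, over 19676 genes, 44% of genes changed by 1 on the log2 scale passed the size rule, and 100% of those changed by 1.5, 2 or 3. Of 19476 unchanged genes, 13 passed it for vemurafenib at 6 h, 18 at 16 h and 90 for the interaction. Of 200 simulated lists of 20 unchanged genes for vemurafenib at 16 h, 0.50% stood apart, and of lists shifted by 0.3, 100% did. The noise was drawn for each gene apart, so the 0.50% does not hold for lists whose genes vary together. In the limma fit of 4 arrays, 100% of genes changed by 1 or by 2 were called among 9651, with 13 false calls. The simulated changes were equal at both times and the noise had the same spread for all genes. This share therefore does not hold for genes whose vemurafenib difference changes with time. For the fits of 6 arrays, changes of 1 and 2 were planted in 100 genes each of the real arrays.

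Alternatives covered thresholds of 1.5-fold and 3-fold, no floor and a floor of log2 8, other ways to combine probe sets, 3 other normalizations, the mean of both DMSO arrays as control, a difference also above that of the DMSO pair, and limma. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 were used. AT9283 at 16 h was not analysed here.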

Results

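Gene expression was measured in A375 cells, an established human melanoma cell line with a mutated BRAF gene, on 6 Affymetrix arrays with 1 array per condition. At 6 h the conditions were the solvent DMSO, 10 µM vemurafenib, 100 nM AT9283, and both drugs together. At 16 h they were DMSO and 10 µM vemurafenib. Vemurafenib inhibits mutant BRAF, the kinase that drives ERK signalling in these cells, and AT9283 inhibits several kinases, among them the Aurora kinases and JAK2. The series title names mechanisms of ATF4 expression. ATF4 is the transcription factor of the integrated stress response, which controls genes of amino acid synthesis and transport. The median intensity per array ranged from 19.79 to 21.29, and between 44.7% and 46.1% of 19676 genes lay at or above an intensity of 64. With 1 array per condition, the differences below have no replicate check, and the number of arrays limits their precision. "Rose" and "fell" describe genes over a size rule, a difference of at least 1 on the log2 scale with the higher array at log2 6 or more, which is not a test.

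The DMSO arrays at 16 h and 6 h served as the yardstick without drug, a loose one because the pair also holds time. Over the size rule, 17 genes were higher at 16 h and 8 were lower. CCDC102B rose by 1.96 on the log2 scale, CCNG2, a cyclin of quiescent cells, by 1.74, and BHLHE40, a clock and hypoxia regulator, by 1.56. The mitochondrial gene ND6 fell by 1.87 and the cell cycle factor E2F1 fell by 1.45. The 26 DNA replication genes had a median of -0.20 and the 17 ribosome biogenesis genes of -0.26, at percentiles 0.01 and 0 among 10000 random lists matched on expression. The 20 glycolysis and hypoxia genes had a median of 0.12 at percentile 99.99. Whether the 6 h and 16 h arrays were normalized together is not given in the sources used here, so time and processing cannot be told apart in this pair.

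**Figure D1:**
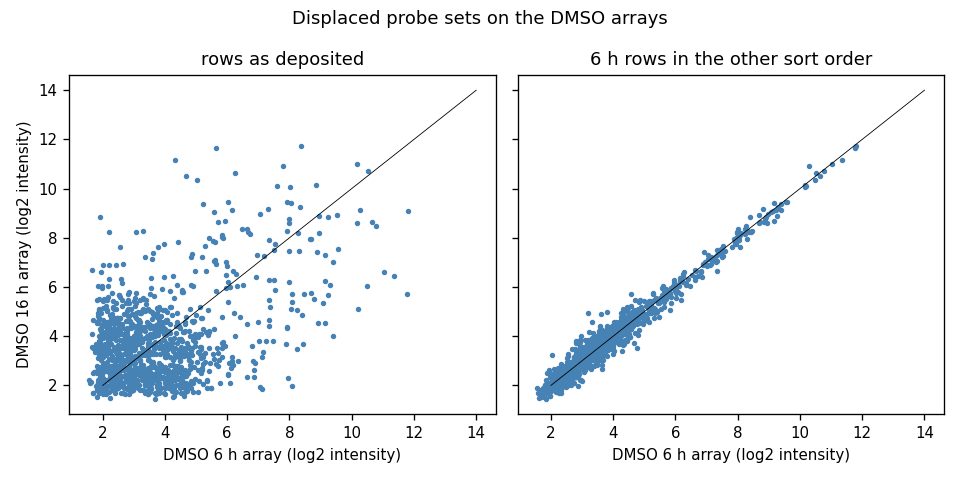
Each point is 1 of 1118 probe sets whose 6 h values sat on another row, with the log2 intensity of the DMSO array at 6 h on the horizontal and at 16 h on the vertical axis. The r was 0.455 as deposited (left) and 0.984 with the 6 h values in the other sort order (right), and these probe sets were left out of the comparisons.

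After 6 h of vemurafenib, 195 genes fell and 94 rose. DUSP6, a phosphatase induced by ERK, had the lowest difference, at 37.4-fold (log2 -5.23), and its other probe sets reached -7.26. Its vemurafenib array lay at log2 4.28, and 76 of the 195 falling genes lay below the floor of log2 6 under vemurafenib, so the size and order of such falls depend on values near background. Other genes of the ERK output list fell with it, among them the feedback inhibitor SPRY2 (-4.06), IER3 (-3.93), DUSP4 (-3.61), the cyclin CCND1 (-2.58), the transcription factors ETV5 (-2.24) and MYC (-2.13), and SPRY4 (-1.42). Of the 22 ERK output genes measured, 17 fell and 0 rose, with a median of -2.23. The chemokine CXCL8 (-4.28), the receptor TLR4 (-3.73), MAFF (-3.67) and ADGRF1 (-3.43) were the other genes among the 8 lowest.

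Of the 94 genes that rose after 6 h of vemurafenib 17 were on the ATF4 lists. Among them CHAC1, which degrades glutathione, rose 10.3-fold (log2 3.36), the stress regulator NUPR1 by 3.26, INHBE by 3.83 and CTH, the enzyme that makes cysteine from cystathionine, by 3.20. The 4 lists of ATF4 program genes held 58 measured genes, of which 17 rose, 0 fell and 54 had a positive difference, with a median of 0.57 at percentile 100. Among the 22 stress regulators 9 rose, with JDP2 at 2.99, DDIT3, which encodes CHOP, at 2.08 and SESN2 at 2.08. Among the 12 genes of amino acid synthesis 6 rose, among them ALDH1L2 at 2.25, PSPH at 2.05, asparagine synthetase ASNS at 1.94 and PSAT1 at 1.12. The cystine transporter SLC7A11 rose by 1.91 and SLC1A4 by 1.76, the 2 of 12 amino acid transport genes to do so. None of the 12 tRNA charging genes passed the size rule on the probe set used, yet all 12 had a positive difference, with a median of 0.46. A second probe set of SARS1, also at the floor, had 1.55 against 0.72 on the one used. ATF4 itself had a difference of 0.99 and TRIB3 of 0.92, both just under the rule. The highest difference was that of ECM2 (3.91), which is not on these lists, and the sialyltransferase ST8SIA4 (3.20), the transcription factor SOX2 (3.02) and CD24 (3.01) were also among the 8 highest.

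Other groups moved less after 6 h of vemurafenib. The 14 JAK-STAT feedback targets had a median of -0.32 at percentile 0, with SOCS3 (-1.81) and BCL2L1 (-1.18) falling, whereas at 16 h the median was -0.06 at percentile 17.2. The 17 p53 targets had a median of 0.33 at percentile 100, although none rose and AEN fell by 1.23. The 17 ribosome biogenesis genes had a median of -0.28 at percentile 0, and none passed the size rule. The 25 mitosis genes had a median of 0.18 at percentile 99.99, none over the rule, and AURKA, AURKB and CCNB1 had differences of -0.02, -0.01 and -0.01. The 19 ER chaperone genes had a median of -0.01 at percentile 28.3, with HSPA5 at 0.11. XBP1 had a difference of 1.01, but it was under the size rule in all 3 other normalizations (0.97 to 0.998). The mean over its 2 probe sets was 0.40, but the other probe set (-0.20) lay below the floor on both arrays. MCL1, a survival factor, fell by 1.28 and the heme oxygenase HMOX1 rose by 1.04. Of the 94 genes that rose, 42 lay below the floor in DMSO, INHBE (log2 2.49) and ECM2 (3.73) among them, so the size of their rise depends on values near background. Without probe sets marked as shared or cross-hybridizing, the differences of ASNS and SLC1A4 were 0.31 and 0.04, that of ASNS on a probe set below the floor.

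After 16 h of vemurafenib, 491 genes rose and 548 fell. DUSP6 (-5.22), CXCL8 (-4.60), IER3 (-4.03), SPRY2 (-3.98) and ADGRF1 (-3.89) were again among the 8 lowest, now with the collagen gene COL13A1 (-4.97), SH2D1B (-4.03) and ETV5 (-3.86). All of these but IER3 lay below the floor under vemurafenib, as did 171 of the 548 falling genes, and 246 of the 491 rising genes lay below it in DMSO, so the size and order of such differences depend on values near background. Of the 22 ERK output genes 19 fell, with a median of -3.02, and CCND1 and MYC fell by 3.52 and 3.30. The 26 DNA replication genes had a median of -1.52 at percentile 0 and 21 of them fell, among them CCNE2 (-3.26), MCM10 (-3.16), CDC25A (-2.63) and CDC6 (-1.76). At 6 h the same list had a median of -0.06 with none over the rule. Of 25 mitosis genes only KIF23 (-1.04) fell, and the list median was -0.36 at percentile 0.98. Of 17 ribosome biogenesis genes 6 fell, NOP16 (-1.47) and RRS1 (-1.31) the most, with a median of -0.92.

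The ATF4 program remained high at 16 h in part. NUPR1 (4.83), INHBE (4.53), ALDH1L2 (3.17), ASNS (2.62), CTH (2.18), CBS (2.15) and DDIT3 (1.70) rose, while CHAC1 rose by 1.18, and SESN2 had a difference of 0.83. Of the 58 genes 16 rose and the median was 0.50, or 0.26 without shared or cross-hybridizing probe sets. Amino acid synthesis (median 1.07, 6 of 12 genes rising) and tRNA charging (0.59, 3 of 12, with WARS1 at 1.51, SARS1 at 1.32 and AARS1 at 1.16) stood above random lists, whereas amino acid transport had a median of 0.04 at percentile 71.2. MGP (5.51), CD24 (5.37), KRT13 (4.49), STON1 (4.09), MAP1LC3C (4.08) and ACKR3 (3.96) were the other genes with the highest differences. Without shared or cross-hybridizing probe sets MGP differed by 1.04. ASNS then differed by -0.092, on a probe set below the floor on both arrays, so this value does not decide its direction. The interferon list had a median of 0.47 at percentile 99.9 with IRF9 (1.90) and IFIT1 (1.76) rising, and the lysosome and autophagy list one of 0.45 at percentile 99.99 with NEU1 (1.01) rising. The p53 list had a median of 0.41 with TP53INP1 (2.67), CDKN1A (1.09) and ZMAT3 (1.09) rising and AEN (-1.69) falling. In the undifferentiated melanoma list NT5E (-3.55), IGFBP3 (-2.97) and EGFR (-1.10) fell and FOXD3 (2.84) rose, with a median of -0.54 at percentile 0.09. Among pigment cell genes GPNMB (1.93) and ERBB3 (1.08) rose, CDK2 (-1.32) fell, and MITF had a difference of 0.63. The pro-apoptotic BMF rose by 1.78, whereas MCL1 and PMAIP1 fell by 1.25 and 1.23. The NRF2 list stood at 0.25, percentile 99.52. The basal keratins KRT14 (1.38) and KRT5 (1.24), markers of other lineages, rose. The split of 491 to 548 depends on scaling, since centring each array on its median gave 370 genes higher and 741 lower with a shift of -0.13 in the median of all genes.

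**Figure D2:**
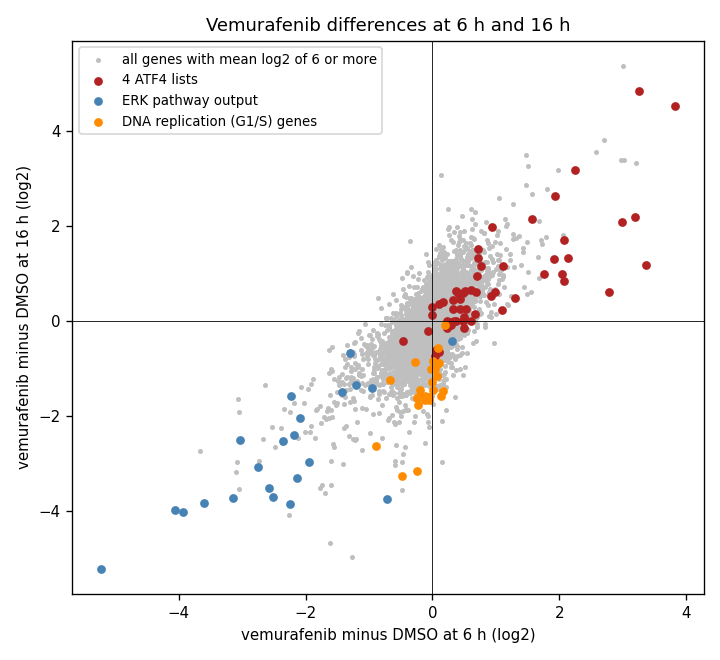
Each point is a gene, with its vemurafenib minus DMSO difference at 6 h on the horizontal and at 16 h on the vertical axis, both in log2. ATF4 list genes lie mostly to the upper right, ERK output genes to the lower left, and DNA replication genes near 0 at 6 h (median -0.06) and below 0 at 16 h (median -1.52).

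The times can be set against each other because they share no array. Among 8913 genes at the floor in both comparisons, 71 of the 93 genes that rose at 6 h also rose at 16 h, where 3.12 would be shared by independent lists. Of the 185 that fell at 6 h, 143 also fell at 16 h, against 11.0, and 0 genes moved in opposite directions. Across 8885 genes, which are not independent replicates, the differences had a Pearson r of 0.722 and a Spearman rho of 0.671. A limma fit of the 4 arrays with time as a block, leaving 1 residual degree of freedom, called 113 genes at an adjusted p under 0.05, 32 higher and 81 lower. In that fit DUSP6 was lower by -5.22 (SE 0.13, adjusted p 0.00517), DDIT3 higher by 1.89 (SE 0.17, adjusted p 0.0295) and ASNS by 2.28 (SE 0.21, adjusted p 0.0311). ATF4, at 0.80 (SE 0.13), had an adjusted p of 0.0901, and CHAC1, at 2.27 (SE 0.54), one of 0.148. The residual of this fit is the change of the vemurafenib difference between the times and not replicate error. CHAC1, for example, went from 3.36 at 6 h to 1.18 at 16 h.

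**Figure D3:**
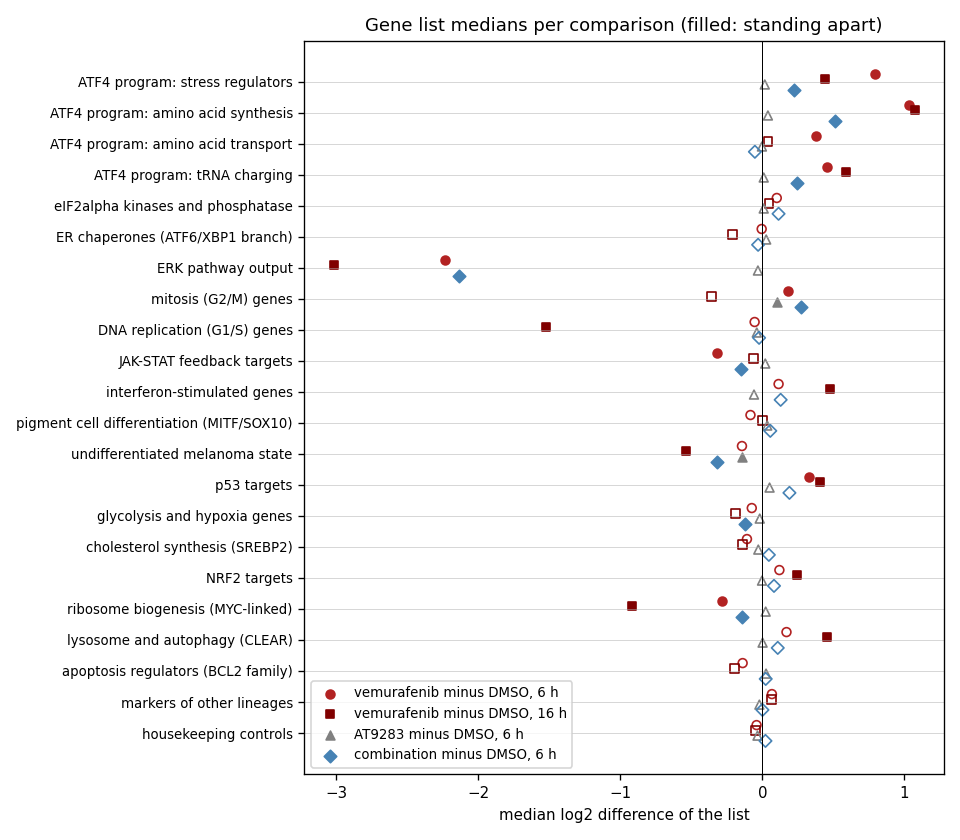
The horizontal axis gives the median log2 difference of each of the 22 gene lists, with 1 marker per comparison with DMSO. Filled markers lie among the lowest or highest 0.5% of random lists, and the largest shifts are those of ERK output (-2.23 and -3.02 under vemurafenib at 6 h and 16 h).

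AT9283 alone at 6 h put few genes over the size rule, as 2 rose and 0 fell. FLG, which encodes filaggrin, rose by 1.22, but it differed by -2.49 between the DMSO arrays. The other was LOC100190986 (1.18), named after its value was seen. ATF4, DDIT3, ASNS, CHAC1 and DUSP6 had differences of -0.00, 0.06, -0.06, -0.28 and -0.15. The mitosis list had a median of 0.10 at percentile 100, with AURKA at 0.13, CCNB1 at 0.16 and AURKB at -0.03. The undifferentiated melanoma list had a median of -0.15 at percentile 0.03, which turned to 0.083 at percentile 87.9 with the mean of both DMSO arrays as control. The JAK-STAT feedback list had a median of 0.02, with SOCS3 at -0.05. The ATF4 and ERK lists had medians of 0.01 and -0.03, at percentiles 64.3 and 7.62. The SD across genes at the floor was 0.13, below the 0.24 of the DMSO pair. Small differences were shared with the combination against vemurafenib, a comparison with no array in common, with an r of 0.427 across 8885 genes and a covariance of 0.01002, against 0.00009 simulated without effect. A limma fit of main effects over the 6 arrays called 0 genes for AT9283, but it averages AT9283 alone with the combination against vemurafenib, and of 100 changes of 2 planted on the AT9283 array alone it recovered 0%, so it does not inform on AT9283 alone.

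Under vemurafenib with AT9283, 175 genes fell and 58 rose relative to DMSO at 6 h. ERK output genes fell as under vemurafenib alone, DUSP6 by 5.12, SPRY2 by 4.24 and DUSP4 by 3.85, and 17 of 22 passed the rule with a median of -2.14. MAFF (-4.53), CXCL8 (-4.09), ANKRD1 (-3.92), IER3 (-3.78) and TLR4 (-3.72) fell too. Here 69 of the 175 falling genes lay below the floor in the combination and 36 of the 58 rising genes in DMSO. The highest differences were those of SOX2 (3.26), ST8SIA4 (2.98), CD24 (2.81), the thioredoxin inhibitor TXNIP (2.45), VAV3 (2.43), ID2 (2.37), PDE4B (2.11) and TRIM6 (2.10), with no ATF4 list gene among these 8. Of the 58 ATF4 list genes 7 rose, among them CHAC1 (1.89), JDP2 (1.85), NUPR1 (1.66), CTH (1.51), ALDH1L2 (1.30), SESN2 (1.27) and PSPH (1.14), and the median was 0.22. DDIT3, ASNS and SLC7A11 had differences of 0.96, 0.70 and 0.83, under the rule, and TRIB3 of -0.00. The JAK-STAT feedback list had a median of -0.15 at percentile 0.40 with SOCS3 (-1.70) and BCL2L1 (-1.02) falling, and the mitosis list one of 0.27 at percentile 100. In the undifferentiated list JUN (-2.18), WNT5A (-1.08) and EGFR (-1.06) fell, with a median of -0.32. The combination and vemurafenib alone shared 38 rising and 152 falling genes among 8994 at the floor in both, against 0.456 and 3.79 for independent lists. Both were set against the same DMSO array, so part of that excess may come from it; the covariance of the differences was 0.126, and 0.0268 in a simulation of unchanged arrays.

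The combination was then set directly against vemurafenib alone at 6 h. All 29 genes over the size rule were lower in the combination, and 12 of them belonged to the ATF4 lists. The 29 were 0.32% of the genes at the floor, near the 0.28% of the DMSO pair, where 17 genes were higher and 8 lower. That pair also holds time and perhaps processing, so it is a loose yardstick. AT9283 against DMSO, both at 6 h, put 0.02% over the rule. The count by itself therefore does not decide whether there was a drug effect. INHBE fell by 2.74, CTH by 1.69, VLDLR by 1.65, NUPR1 3.01-fold, CHAC1 by 1.47, SLC1A4 by 1.24, ASNS by 1.23, DDIT3 by 1.12 and SLC7A11 by 1.08. For 11 of the 29 genes the combination array lay below the floor, INHBE (log2 3.57) and VLDLR (5.46) among them, so the size and order of these falls depend on values near background. Of the 58 ATF4 list genes 56 were lower, with a median of -0.46 at percentile 0. The 4 lists had medians of -0.81 for stress regulators, -0.53 for amino acid synthesis, -0.49 for transport and -0.21 for tRNA charging, all at percentile 0. ATF4 itself differed by -0.38, TRIB3 by -0.92, SESN2 by -0.81 and PSAT1 by -0.58. The other genes among the 8 lowest were ECM2 (-1.97), S100P (-1.89), RAB39B (-1.76) and UBALD2 (-1.48). JUN fell by 1.14 below its level under vemurafenib. ETV5 and CCND1 differed by 0.32 and 0.59, and MYC, DUSP6 and SPRY4, which lay below the floor on both arrays, by -0.95, 0.11 and 0.25. The ERK output list had a median of 0.08 at percentile 90.3, but only 12 of its 22 genes reached the floor on either array and so could pass the rule, and none of these did. The mitosis list was higher, with a median of 0.13 at percentile 99.97. Of the 29 genes 19 had risen under vemurafenib alone at 6 h and 14 had risen at 16 h. Without shared or cross-hybridizing probe sets, ASNS, SLC1A4 and JUN differed by -0.26, -0.43 and -0.56, ASNS on a probe set below the floor.

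**Figure D4:**
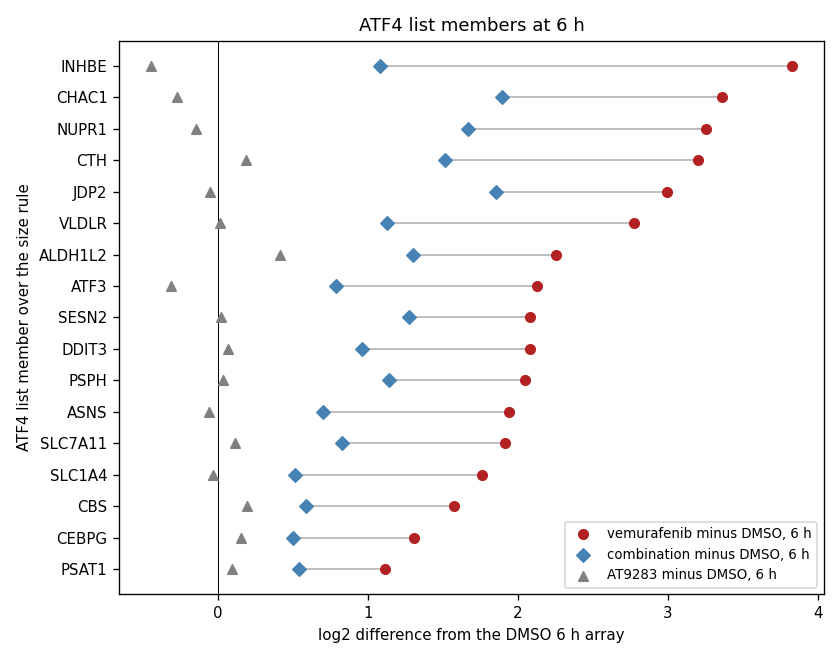
The rows are the 17 ATF4 list genes that rose under vemurafenib at 6 h, and the horizontal axis is the log2 difference from the DMSO 6 h array under vemurafenib, AT9283 or both. All 17 lie closer to 0 in the combination than under vemurafenib alone, and in the combination they kept a median of 46.1% of their difference. Several, INHBE and VLDLR among them, lay below the floor of log2 6 in DMSO.

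These 17 genes kept a median of 46.1% of their vemurafenib difference in the combination (quartiles 37.4% and 55.8%). INHBE, VLDLR, NUPR1, JDP2, SLC1A4, CHAC1 and ALDH1L2 among them lay below the floor in DMSO. INHBE, VLDLR and SLC1A4 also lay below it in the combination, so the share kept depends in part on values near background. The 17 ERK output genes that fell at 6 h kept 94.5% (quartiles 85.9% and 100.4%). Several of them, DUSP6, SPRY2, MYC and SPRY4 among them, lay below the floor under vemurafenib and in the combination. Near background a change by AT9283 is hard to see, so the contrast with 46.1% may be set in part by the floor. Genes chosen on the vemurafenib 6 h array tend to shrink on any other array, so the members were also chosen on the 16 h arrays. The 16 ATF4 list genes that rose at 16 h had a median of 2.01 under vemurafenib at 6 h, 0.81 in the combination and -0.05 under AT9283, and a median of -1.10 between combination and vemurafenib at percentile 0. For all 491 genes that rose at 16 h the medians at 6 h were 0.47 under vemurafenib, 0.39 in the combination and -0.00 under AT9283, and the combination lay at -0.08 from vemurafenib. For the 548 that fell they were -0.53, -0.42 and 0.01, and the combination lay at 0.11 from vemurafenib. Both of those shifts lay outside all 10000 random sets, at percentiles 0 and 100.

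Read against AT9283 alone, 41 genes rose and 179 fell in the combination. SOX2 (3.12), CD24 (2.85), ST8SIA4 (2.73) and CHAC1 (2.17) rose the most, and DUSP6 (-4.96), SPRY2 (-4.22), CXCL8 (-4.20) and MAFF (-4.12) fell the most. These differences and those of vemurafenib against DMSO share no array, and their r across 8885 genes was 0.895, with 35 rising and 150 falling genes in both. The vemurafenib difference was lower with AT9283 than without it by at least 1 on the log2 scale for 26 genes and higher for 0. For 24 of the 26 the difference without AT9283 was positive, and the other 2, FLG and AMIGO2, the latter named after its value was seen, had -1.46 and -0.64. INHBE (-2.30), ECM2 (-2.14), S100P (-1.90), CTH (-1.87), VLDLR (-1.66), NUPR1 (-1.45), ALDH1L2 (-1.36) and GDF15 (-1.36) had the lowest interaction values. Of these INHBE, ECM2, VLDLR, NUPR1 and ALDH1L2 lay below the floor on the DMSO and AT9283 arrays, so their size and order depend on values near background. Stress regulators had a median interaction of -0.89, amino acid synthesis of -0.64, transport of -0.40 and tRNA charging of -0.27, all at percentile 0, and ERK output of 0.05 at percentile 78.2. The other lists that stood apart went the other way, ribosome biogenesis with 0.11 at percentile 99.93 and DNA replication with 0.086 at percentile 99.62. The interaction sums the error of 4 arrays. A simulation of unchanged genes with the spread of the DMSO pair put 90 of 19476 genes over the rule, more than the 26 seen, so that spread is too wide for the 6 h arrays and sets no bound here. The highest interaction value among genes at the floor was 0.83. A limma fit with the interaction, added after seeing the data, called 0 of 9707 genes, and it recovered 1% of 100 planted interactions of 2, so it does not decide. GDF15 had 0.018 without shared or cross-hybridizing probe sets, on a probe set below the floor under DMSO and vemurafenib.

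Several lists did not stand apart in the main comparisons. The eIF2α kinase and phosphatase list had medians of 0.10, 0.05, 0.01 and 0.11 under vemurafenib at 6 h, vemurafenib at 16 h, AT9283 and the combination, although EIF2S1, which encodes eIF2α, fell by 1.02 at 16 h. Cholesterol synthesis genes had medians of -0.11, -0.14, -0.03 and 0.05 in the same order, and BCL2 family genes of -0.14, -0.20, 0.03 and 0.02. Pigment cell genes had medians of -0.08, 0.00, 0.03 and 0.06, but at most 8 of the 19 measured reached the floor in these comparisons. Glycolysis and hypoxia genes had medians of -0.08, -0.19 and -0.02 under the single drugs, and -0.12 at percentile 0.04 in the combination. The glucose transporter SLC2A3 fell by 1.52 in the combination and by 1.65 and 1.83 under vemurafenib alone at 6 h and 16 h. Markers of other lineages had medians of 0.07, 0.07, -0.02 and 0.00, and housekeeping genes of -0.04, -0.05, -0.03 and 0.02. At most 3 of the 15 lineage markers measured reached the floor, so their medians mostly describe background. The interferon list at 6 h had medians of 0.11, -0.06 and 0.13 under vemurafenib, AT9283 and both, the NRF2 list of 0.12, -0.00 and 0.08, and the lysosome list of 0.17, 0.00 and 0.11. ER chaperones had medians of -0.21 at 16 h, where SDF2L1 fell by 1.28, and of 0.03 and -0.03 under AT9283 and both drugs. Over the 22 lists and 7 comparisons, 49 of 154 medians stood apart, where 1.54 would by chance if the genes of a list varied independently. Of the 49, 3 were in the DMSO pair, where no drug differed. Time, processing or shared variation of a list's genes can thus set medians apart, and 1.54 is too low a reference for drug effects.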

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

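All tests in this part were chosen after the results were seen. Only the reading of all genes that rose or fell at 16 h on the 6 h arrays was fixed before. Its restriction to the ATF4 list members, used below, was not.

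The displaced rows hold signal that the comparisons do not use. As deposited, 299 of the 1118 displaced probe sets differed by more than 2 on the log2 scale between the DMSO arrays, against 5 of 53495 others. With the 6 h values in the other sort order, 0 did, which the explanation of a different row order needed. A longer time in culture would spread such probe sets over the whole table, but 98.4% of them lay inside blocks that hold 2.05% of the probe sets. Read on the restored rows, PCK2, an ATF4 target, had a vemurafenib difference of 2.07 at 6 h, and DDIT4 of 1.28, and in the combination they lay at -1.42 and -0.88 from vemurafenib. The CXCL8 probe set there had -4.71 at 6 h and -5.16 at 16 h. As deposited, the -4.71 stands on the row of DENND4B and the 2.07 of PCK2 on the row of GRK6, genes named after their values were seen, so both would be read as responding to vemurafenib. At which step the order changed was not tested.

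The ATF4 lists lay lower in the combination than under vemurafenib alone. Weaker vemurafenib action on all targets would shrink other genes alike, yet the 486 genes called at 16 h outside the ATF4 and ERK lists that moved the same way by 0.5 or more at 6 h kept a median of 83.8% (quartiles 63.9% and 100.3%), and the 219 of them that rose 78.7% (52.2% and 101.3%). The 16 ATF4 members that rose at 16 h, all of which meet the same minimum, kept 46.7%. INHBE, NUPR1, JDP2, CHAC1 and ALDH1L2 among them lay below the floor in DMSO at 6 h, so their shares depend on values near background. Without the minimum, the median in the combination was 81.3% of that under vemurafenib for all 1004 such genes and 40.2% for the ATF4 members. This argues against a weaker action on all targets alike. A weaker action on part of them stays open, since the ribosome biogenesis median also shrank, from -0.28 to -0.15, with an interaction of 0.11 at percentile 99.93. Return to the mean is argued against by those members, which were chosen on other arrays and lay at -1.10, and array scaling by the median of -0.44 or lower under 3 other normalizations. A lower vemurafenib exposure that still saturates ERK output cannot be told apart from an action of AT9283. The ERK genes that fell at 16 h kept 96.0% and may be at their limit, and several lay below the floor on both treated 6 h arrays. Across 8885 genes AT9283 alone and the combination against vemurafenib shared small differences (r 0.427), while the ATF4 lists had a median of 0.01 under AT9283 alone. An effect of AT9283 on ATF4 target expression remains a hypothesis, since it was found and weighed on the same arrays, and the limma fit with an interaction called 0 genes while recovering 1% of planted interactions of 2.

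Of the 26 genes with an interaction over the size rule 5 had vemurafenib differences of opposite sign without and with AT9283, and these differences were not tested. For KLF4, STC2 and TRIB3 the smaller difference was under the simulated array SD of 0.16 in size, so its sign is not settled. GDF15 went from 0.50 to -0.86, an interaction of -1.36. It was 0.018 without shared or cross-hybridizing probe sets, on a probe set below the floor under DMSO and vemurafenib. For HOXB9 the differences were 0.87 and -0.40, an interaction of -1.27. KLF4 had 0.09 and -1.11, an interaction of -1.21. For STC2 the values were 0.11 and -0.94, an interaction of -1.05. TRIB3 had 0.92 and -0.09, an interaction of -1.001. HOXB9, KLF4 and STC2 were named after their values were seen. GDF15, STC2 and TRIB3 are members of the ATF4 stress regulator list.

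The mitosis list had opposite medians at the 2 times, 0.18 at 6 h and -0.36 at 16 h, and the difference between the times was not tested.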

How the results depend on the processing

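Keeping the displaced probe sets as deposited, restoring their order, and the limma fit with an interaction were chosen after seeing the data. All other alternatives were fixed before. Of the counts under alternatives 74 stayed within 1.5 times the main count and 53 did not. Counts are given in the order vemurafenib 6 h, vemurafenib 16 h, AT9283, combination against DMSO, against vemurafenib, against AT9283, DMSO pair, interaction, and both times. The main counts were 289, 1039, 2, 233, 29, 220, 25, 26 and 214. A 1.5-fold threshold gave 761, 2646, 15, 619, 108, 582, 241, 117 and 573, a 3-fold threshold 117, 349, 0, 88, 7, 92, 4, 5 and 88, and a floor of log2 8 gave 143, 525, 0, 105, 13, 104, 6, 12 and 102. Asking for at least 2 probe sets of the gene over the rule gave 109, 318, 0, 90, 9, 80, 3, 8 and 76, which only the 10378 genes with 2 or more can meet. These shifts follow from a looser or stricter rule. The mean over all probe sets moved 7 counts, to 186, 675, 1 for AT9283, 143 against DMSO, 134 against AT9283, 10 for the DMSO pair and 134 at both times. Without a floor AT9283 had 4 genes, the DMSO pair 120 and the interaction 47. A difference also above that of the DMSO pair left 1 gene for AT9283, without FLG. With displaced probe sets as deposited the DMSO pair had 79 genes, 34 higher and 45 lower against 17 and 8. Limma called 113 genes for a vemurafenib effect common to both times, which does not ask for a call at each, 463 for the vemurafenib main effect and 0 for AT9283. With the interaction in the fit, it called 0 for AT9283 and 0 for the interaction. In the real arrays the fit of main effects recovered 54% and 90% of changes of 1 and 2 planted on both AT9283 arrays, so its 0 calls argue against many shared changes of 2. It recovered 0% of those on AT9283 alone, and the fit with the interaction 2% for AT9283 and 1% for the interaction, so changes by AT9283 alone and interactions stay undecided in these fits. Centring on the array median gave 15 genes higher and 12 lower in the DMSO pair, and using the mean DMSO control AT9283 had 2 and 1. All 29 genes lower in the combination than under vemurafenib remained so under median centring, quantile normalization and loess. The mean over probe sets kept 22 of the 29. Leaving out shared or cross-hybridizing probe sets kept 21, and 1 gene was then higher.

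The median of the ATF4 lists between combination and vemurafenib ranged from -0.48 to -0.43 over 7 alternatives, and under vemurafenib from 0.52 to 0.63 at 6 h and from 0.26 to 0.57 at 16 h over 8, lowest at 16 h without shared or cross-hybridizing probe sets. ERK output ranged from -2.33 to -2.11 at 6 h and from -3.15 to -2.27 at 16 h. With the mean of both DMSO arrays as control, genes that rose and fell at 16 h had medians of -0.085 and 0.075 under AT9283, now outside random sets. Under the same control the undifferentiated list turned to 0.083 under AT9283 and ribosome biogenesis to 0.033 in the combination, for reasons not tested. Of the other list medians 10 no longer stood apart and 22 newly did. Without shared or cross-hybridizing probe sets ASNS turned to -0.092 at 16 h and the GDF15 interaction to 0.018. The ASNS probe set used there lay below the floor at both times, and that of GDF15 under DMSO and vemurafenib at 6 h. These values therefore do not decide the direction. The cause was not tested beyond the change of probe set. Of named gene values 94 dropped below the size rule, 51 of them with the mean over probe sets, and 6 newly passed it. No paired analysis was possible because no replicate numbers pair the arrays. The limma fit with time as a block matches vemurafenib with DMSO by time only. Genes below log2 6 are limited by signal over background, and 246 of the 491 genes that rose at 16 h lay below it in DMSO.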

Other observations

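The test in this part was chosen after the results were seen.

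Under vemurafenib some genes kept their rise when AT9283 was added. SOX2 differed by 3.02 under vemurafenib and 3.26 in the combination, VAV3 by 2.18 and 2.43, CD24 by 3.01 and 2.81, and ST8SIA4 by 3.20 and 2.98. TXNIP, an inhibitor of thioredoxin, had 2.71 and 2.45, and the differentiation regulator ID2 2.98 and 2.37. At 16 h of vemurafenib these 6 genes stood at 3.39, 3.55, 5.37, 3.33, 3.81 and 3.38. FST and CCN2, named after their values were seen, fell further in the combination, to -3.15 from -1.75 under vemurafenib alone and to -2.94 from -1.77, and with vemurafenib alone at 16 h they had -3.45 and -3.51.

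The ATF4 genes that rose early did not all follow the same course over time. CHAC1 went from 3.36 at 6 h to 1.18 at 16 h, VLDLR from 2.78 to 0.60 and SESN2 from 2.08 to 0.83, whereas NUPR1 went from 3.26 to 4.83 and ALDH1L2 from 2.25 to 3.17. The DMSO pair differed by 1.35 for VLDLR, from a log2 value of 4.33 at 6 h to 5.68 at 16 h, so its course mixes control and drug.

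A hypothesis was that the rise of the ATF4 lists at 6 h belongs to an unfolded protein response that includes its chaperone branch. It would need the ER chaperone list to lie above random lists at 6 h, yet its median was -0.01 at percentile 28.3. The chaperones were also set against the ATF4 lists, whose median was 0.57, although the hypothesis does not require a rise of that size. The upper quartile of the chaperone list was 0.073 and 2 of 19 reached 0.57, among them XBP1, a member of the list, at 1.01. The mean over the 2 XBP1 probe sets was 0.40, but 1 of them lay below the floor. The chaperone values argue against a response with its chaperone branch at the mRNA level at 6 h. Activation of the eIF2α kinases by another route was not measured by these arrays and stays open.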
